A study of Mus musculus with 8 samples.

How the data were processed

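RNA from posterior palatal shelves of E14.5 mouse embryos was sequenced in 8 libraries, and the libraries were put into 4 controls and 4 Col2Cre mutants as the labels give them. Replicates were numbered in the order of the labels, and every column of the table was assigned to a library. The deposited table held 55536 genes with a normalised count and a variance-stabilised value for each library. STAR 2.7.2 and DESeq2 are named in the submitters' notes, DESeq2 without a version; the counting tool, strand setting, annotation and genome build are not given in the sources used here. Gene starts and ends equalled those of the GENCODE annotation of GRCm38 for 49995 of 52489 gene IDs found in both (95.2%). The 3047 IDs without a symbol in the table were named from that annotation by ID, and 86 symbols stood on several IDs.

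The signal values were made by the authors as normalised counts, gene read counts divided by 1 size factor per library and rounded to 1 decimal. This was checked by looking for a step per library that turns the values into whole reads: 99.7% to 100% of values between 50 and 5000 were whole within 0.05 reads, where rounding alone gives about 10.2% in control replicate 2. The recovered totals were 29025089 to 32437977 reads per library and the size factors 0.939 to 1.06. The log2 values were made by the authors as variance-stabilised values on a scale close to log2, deposited with a floor of 9.47 for genes without reads, and were used in 1 alternative only. At this depth a gene with 0 reads could have had up to 3 reads in a library, a limit that covers counting error only. Genes with 0 in all libraries numbered 26661.

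The comparison of mutants with controls was fitted with limma 3.58.1 in R 4.3.3 on log2(normalised count + 1), with an intensity trend in the variances and genotype as the only term. The 16647 genes with a normalised count of at least 10 in at least 4 of the 8 libraries were tested, two-sided, with Benjamini-Hochberg adjustment at 0.05. Genes changed by more than 2-fold were those past that threshold with an absolute log2 difference of at least 1. Yap1, Wwtr1 and list means were also tested with exact two-sided permutation of the 8 libraries, in which 4 against 4 cannot give a p below 0.0286. Values are means with the SD over libraries, and SE is that of the limma log2 difference.

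Gene lists for signalling, matrix, patterning, stress and the cell types that the dissection could hold were tested with limma's camera at a preset correlation of 0.01, two-sided and adjusted over the 29 lists with at least 5 tested members. Camera was repeated with an estimated correlation, and fry tested whether a list's genes moved one way or in either direction. Genes to be named were Yap1, Wwtr1 and Col2a1; the 10 genes in each direction with the largest log2 difference among those past the threshold without overlap between the groups, with a mean of at least 50 and leaving out predicted and sex-linked genes; where fewer than 10 qualified, those and the ones with the smallest p, up to 5 in all; and up to 4 tested members of each list with the smallest p. Not every gene that this rule allows is named. The groups, main tests, gene lists, naming rule and most other settings tried were fixed before the data were examined. The alternatives with the stabilised values, with exact permutation of list means and with list members of a mean of at least 50 were chosen after seeing the data.

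The alternatives were pseudocounts of 0.5 and 8, no filter, a mean of at least 50, trimmed mean of M-values, upper-quartile and quantile scaling, library weights, robust variances, the first number of each title as a block, leaving out each library in turn, and edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with numpy 2.4.6 and pandas 2.3.3.

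The test was tried on simulated data in 10 runs with 200 changed genes each among 16647. It called 44.7% of the genes changed 1.5-fold, 66.3% of those changed 2-fold and 84.1% of those changed 4-fold, and 84 of 1385 calls (6.06%) were unchanged genes. The adjusted threshold is easier to reach when many genes change. With 4 genes called in the real data, these shares do not give the power of the real comparison. Camera called an osteogenic list moved by 0.3 on the log2 scale in 10 of 10 runs, with 2 calls of other lists, on simulated genes that vary independently, which real list members do not. Whole reads were recovered for 100% of simulated values between 50 and 5000 in all 8 libraries, and values outside that range were not scored. These trials were first run after the real data had been fitted once. Raw reads were not used here, so floxed exons, strand and splice forms were not examined, and no comparison made by the authors was in the table.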

Results

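Posterior palatal shelves, the paired outgrowths that later form the roof of the mouth, were taken from E14.5 mouse embryos before the shelves had elevated, and their RNA was sequenced. The tissue held epithelium and mesenchyme together. There were 4 control libraries, from embryos with floxed Yap1 and Taz alleles and no Cre, and 4 mutant libraries, from embryos that also carried a Col2Cre transgene, a Cre driven by Col2a1 regulatory sequence. The labels speak of embryos but do not tie each library to a separate animal, so the p-values measure the spread between these samples. Depth was even: the totals recovered from the table ranged from 29025089 to 32437977 reads per library. The comparison of mutants with controls asks which genes differ in the shelves before elevation when embryos with floxed Yap1 and Taz also carry Col2Cre.

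Both targeted genes had lower mean counts in the mutant libraries. Yap1 (ENSMUSG00000053110, chromosome 9 from 7931999 to 8004596), a transcriptional co-activator of the Hippo pathway, had 9610 ± 429 normalised counts (SD, n = 4) in controls and 8463 ± 277 (SD, n = 4) in mutants. Every mutant library lay below every control library for Yap1, a log2 difference of -0.18 (SE 0.0520). Of all genes tested, 3.77% had no overlap between the groups, 318 lower and 309 higher in mutants, against 2.86% by chance. Wwtr1, the gene for TAZ (ENSMUSG00000027803, chromosome 3 from 57455649 to 57575910), had 4879 ± 352 normalised counts in controls and 4007 ± 397 in mutants, a log2 difference of -0.29 (SE 0.0773). Neither passed the limma test over all genes (adjusted p = 0.751 for both). An exact two-sided permutation test gave p = 0.0286 for Yap1, the smallest value that 4 libraries against 4 allow, and p = 0.0571 for Wwtr1. The counts are per gene and do not separate floxed exons from the rest, and the dissected tissue can hold cells without Cre, so they give no estimate of how many cells had lost either gene. Col2a1, the cartilage collagen gene whose regulatory sequence drives the Cre, had 17894 ± 4116 normalised counts in controls and 12072 ± 4318 in mutants (log2 difference -0.62, and -0.36 without mutant replicate 2; limma adjusted p = 0.754).

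**Figure D1:**
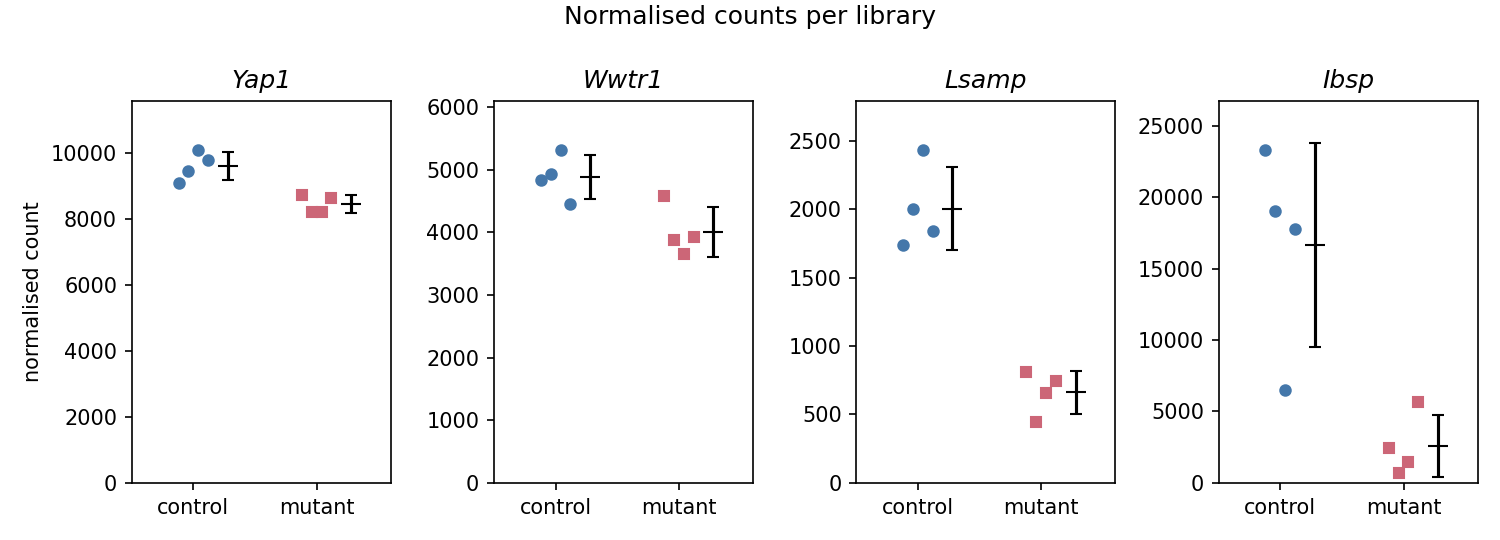
Normalised counts (y axis, starting at 0) of Yap1, Wwtr1, Lsamp and Ibsp in the 4 control libraries (circles) and the 4 mutant libraries (squares), with the mean and SD of each group as a bar beside the points. Lsamp averages 2003 in controls and 662 in mutants with no overlap, while Ibsp spreads widely within both groups.

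Of 16647 genes tested, 4 fell in the mutant libraries and 0 rose (limma, Benjamini-Hochberg adjusted p below the 0.05 threshold), and all 4 fell by more than 2-fold. Lsamp, which encodes a cell adhesion protein of the immunoglobulin superfamily studied in the limbic system, dropped from 2003 ± 304 normalised counts (SD, n = 4) in controls to 662 ± 158 (SD, n = 4) in mutants. Its log2 difference was -1.62 (SE 0.168, limma adjusted p = 0.0108), with all mutant libraries below all control libraries. Lsamp (ENSMUSG00000061080) spans chromosome 16 from 39984361 to 42181679 in the coordinates of the authors' table, whose build is not given in the sources used here but whose gene positions equal those of the mouse GRCm38 annotation for 95.2% of the gene IDs compared. The other called genes are non-coding, and Gm42418 and Gm23935 lie outside the rule for named genes and were chosen after their values were seen. Gm42418 and CT010467.1 lie on opposite strands of one ribosomal RNA locus on chromosome 17 (39846958 to 39848788 and 39846353 to 39848827), where CT010467.1 covers all 1831 bp of Gm42418. Gm42418 took 5.10% ± 0.632 of the reads in controls and 2.08% ± 0.389 in mutants (SD, n = 4 each), and its log2 difference was -1.38 (SE 0.162, limma adjusted p = 0.0156). CT010467.1 had a log2 difference of -1.28 (SE 0.158) and Gm23935, annotated as a microRNA inside Zc3h7a on chromosome 16, one of -1.09 (SE 0.133), both with limma adjusted p = 0.0156. The replication-dependent histone genes, whose messages also lack a poly(A) tail, were looked at after this result was seen, and 40 of 45 tested members had lower means in mutants, with a median log2 difference of -0.80. Gene-wise testing without adjustment gave p below 0.05 for 1093 genes, of which 631 were lower and 462 higher in mutants, against 832 by chance. The limma count went to 0 without control replicate 2, without control replicate 4 or without mutant replicate 3, and to 11 without control replicate 3 and 8 without mutant replicate 4. Without control replicate 1, 3 genes were called, 2 of them among the 4. DESeq2 on recovered whole reads called 31 genes, 28 lower and 3 higher, and edgeR called 5.

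The genes next in line did not pass the main limma test. Under the 22 alternatives run for them, Lars2 passed in 10 and Rn7sk in 7, among them limma with other scalings and DESeq2, which also called Inhba, Maf1, Tgif2 and Pcbp4. Among those lower in every mutant library, Rn7sk, the 7SK small nuclear RNA that holds back transcription elongation, had 776 ± 201 normalised counts in controls and 283 ± 46.9 in mutants (limma adjusted p = 0.0536). Lars2, the mitochondrial leucyl-tRNA synthetase gene, had 23053 ± 3025 and 13100 ± 2023 (limma adjusted p = 0.0561). Whether its reads were part of the ribosomal RNA signal of Gm42418 was examined and stayed undecided. Inhba, which encodes the activin A subunit, had 1348 ± 123 and 921 ± 71.2 (limma adjusted p = 0.170). The 5 genes with the smallest p among those higher in mutants were Maf1, a repressor of RNA polymerase III, Tgif2, a repressor in TGF-beta signalling, Pcbp4, Yrdc and Ppp1r14b. Their log2 differences ran from 0.24 for Pcbp4 to 0.49 for Ppp1r14b, with limma adjusted p from 0.576 for Maf1 to 0.751 for Yrdc and Ppp1r14b.

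Of 29 gene lists fixed in advance, 8 stood apart from other genes in camera with a preset correlation of 0.01, 5 lower and 3 higher in mutants. None of the 8 held with an estimated correlation, in fry for one direction or either, or in exact permutation of the list means after adjustment, where 0 of 29 passed. Other ways of dividing the 8 libraries into 4 and 4 gave up to 11 lists by camera. No list member passed the limma test over all genes. The mutant libraries were also the ones in which the ribosomal RNA locus took the smaller share of reads, 2.08% ± 0.389 against 5.10% ± 0.632 in controls.

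Genes of bone formation had lower mean counts in the mutant shelves. Of 23 tested members of the osteogenic list, 22 had lower means in mutants, and 13 fell when adjusted over the list alone, against 0 adjusted over all genes. Ibsp, bone sialoprotein, a mineral-binding matrix protein, had 16656 ± 7149 normalised counts (SD, n = 4) in controls and 2582 ± 2181 (SD, n = 4) in mutants, a log2 difference of -2.94 (SE 0.535, limma adjusted p = 0.267 over all genes). Ibsp passed under 3 of 22 alternatives, among them leaving out mutant replicate 4 (limma adjusted p = 0.0207) and DESeq2, which also called Cgref1 and Phex of this list and, of other lists, Loxl4, Wif1 and Cald1. Smpd3, a sphingomyelinase needed for bone mineralisation, had 2917 ± 766 and 1245 ± 736. Panx3, a pannexin of osteoblasts and chondrocytes, had 1218 ± 281 and 512 ± 315, and Cgref1 had 202 ± 95.6 and 62.2 ± 18.7. Control replicate 3 lay among the mutants for Cgref1 at 65.7, and its osteogenic level of -0.48 was close to the -0.50 of mutant replicate 4. Cgref1 passed the limma test over all genes without control replicate 3. The mean log2 level of the list differed by -0.98 between mutants and controls (SD 0.420 in controls and 0.434 in mutants, n = 4 each), with all mutant libraries below all controls (exact permutation p = 0.0286, 0.414 after adjustment over 29 lists). Mutant replicate 2 had the lowest osteogenic level of the 8 libraries and also the highest epithelial and erythroid levels, and without it the difference was -0.82. The camera adjusted p was 3.86e-16, against an adjusted p of 0.522 with an estimated correlation.

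Genes of cartilage and collagen matrix also had lower means in most cases. Of 33 members of the collagen and fibrillar matrix list 31 had lower means in mutants, and 0 passed when adjusted over the list alone. The lysyl oxidase gene Loxl4, which acts in collagen crosslinking, had 220 ± 95.9 normalised counts in controls and 64.3 ± 28.0 in mutants, the proteoglycan gene Bgn had 24217 ± 1406 and 19697 ± 2659, the prolyl hydroxylase gene P4ha1 had 5110 ± 442 and 4208 ± 513, and Loxl2 had 4310 ± 503 and 3635 ± 85.2. Control replicate 3 lay among the mutants for Loxl4, at 83.1. The collagen list had a mean log2 difference of -0.24, a camera adjusted p of 8.53e-09 and an adjusted p of 0.522 with an estimated correlation. As for the osteogenic list, its mean log2 level was lower in all mutant libraries than in all controls (exact permutation p = 0.0286, 0.414 after adjustment over 29 lists). The gap was narrow, with -0.104 in mutant replicate 1 and -0.0899 in control replicate 1. Of 20 tested chondrogenic genes 18 had lower means and 0 passed when adjusted over the list alone. Hapln1, a link protein of cartilage matrix, had 638 ± 182 and 363 ± 132, and the cartilage collagen genes Col11a1 and Col11a2 had log2 differences of -0.63 (SE 0.206, and -0.37 without mutant replicate 2) and -1.24 (SE 0.420). The chondrogenic list had a camera adjusted p of 8.84e-05, an adjusted p of 0.614 with an estimated correlation, and 0.142 without control replicate 1, the library with the highest chondrogenic level. Its mean log2 difference was -0.48, and -0.15 without control replicate 1, -0.27 without mutant replicate 2, -0.76 without control replicate 3 and -0.77 without mutant replicate 1.

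Targets of YAP and TAZ had a mean log2 difference of -0.11 over the list, which rested on mutant replicate 4: without that library it was -0.019, and without mutant replicate 3 it was -0.17. Of 22 members of the target signature 16 had lower means in mutants and 0 passed when adjusted over the list alone. Cyr61, a matricellular target, had 1792 ± 111 normalised counts in controls and 1490 ± 97.2 in mutants, and Crim1 had 1631 ± 181 and 1405 ± 45.9, both lower in every mutant library, while Tgfb2 had a log2 difference of -0.19 (SE 0.0783). Crim1 was at -0.14 without control replicate 3 and Tgfb2 at -0.12 without mutant replicate 2. The camera adjusted p was 0.00607, against an adjusted p of 0.562 with an estimated correlation, 0.152 without control replicate 3 and 0.110 without mutant replicate 4. The 24 Hippo pathway components, which include Yap1 and Wwtr1, divided into 11 higher and 13 lower (camera adjusted p = 0.401), with Ajuba at a log2 difference of 0.25 (SE 0.125, and 0.13 without mutant replicate 2) and Wwc2 at -0.13 (SE 0.0665).

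Markers of other cell types that the dissection could hold also differed between the groups in camera. All 24 epithelial and periderm markers had higher means in mutants (camera adjusted p = 1.70e-06, adjusted p = 0.614 with an estimated correlation, 0.0881 without mutant replicate 2). Among them the claudin genes Cldn7 and Cldn4 had log2 differences of 0.63 (SE 0.251) and 0.40 (SE 0.162), and the keratin gene Krt8 one of 0.35 (SE 0.151). Without control replicate 2 Cldn7 was at 0.35 and Krt8 at 0.23, and without mutant replicate 2 Cldn4 was at 0.26. Endothelial markers were lower in 15 of 18 cases (camera adjusted p = 2.89e-05, adjusted p = 0.614 with an estimated correlation). Cdh5, VE-cadherin, had 6285 ± 364 normalised counts in controls and 5219 ± 635 in mutants, and Emcn and Pecam1 had log2 differences of -0.28 (SE 0.0971) and -0.22 (SE 0.0813), the latter -0.14 without mutant replicate 2. Schwann cell and neural crest glia markers were higher in 10 of 12 cases (camera adjusted p = 0.00269, adjusted p = 0.562 with an estimated correlation, 0.351 without mutant replicate 1), with Erbb3, a neuregulin receptor, at 2138 ± 166 and 2873 ± 548, and the neural crest transcription factor genes Foxd3 and Sox10 at 103 ± 40.8 and 199 ± 63.5, and 467 ± 86.2 and 734 ± 408. The log2 difference of Sox10 went from 0.53 to 0.20 without mutant replicate 1, and that of Foxd3 was 0.65 without control replicate 2. Erbb3 passed over all genes without mutant replicate 4 (limma adjusted p = 0.0267). Erythroid markers were higher in 12 of 14 cases (camera adjusted p = 0.0154, adjusted p = 0.614 with an estimated correlation). The alpha-globin genes Hba-a2 and Hba-a1 had log2 differences of 0.69 (SE 0.246) and 0.59 (SE 0.218). The erythroid call was lost in camera without control replicate 1 (adjusted p = 0.142), mutant replicate 2 (0.150) or mutant replicate 3 (0.0923). No member of these 4 lists passed when adjusted over its list alone. Mutant replicate 2 had the lowest mean log2 level of the 8 libraries for the osteogenic (-1.46), chondrogenic (-1.11), collagen (-0.45) and endothelial (-0.43) lists and the highest for the epithelial (0.76) and erythroid (0.75) lists, and it was the library with Xist at 840.4 normalised counts, against 0 to 17.4 in the others. Without it the mean log2 difference went from -0.16 to -0.065 for the endothelial list, where camera gave an adjusted p of 0.0472, from 0.25 to 0.077 for the epithelial list and from 0.28 to 0.13 for the erythroid list. The epithelial difference was 0.14 without control replicate 2, the erythroid one 0.48 without mutant replicate 1, and the Schwann cell one went from 0.36 to 0.12 without mutant replicate 1.

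**Figure D2:**
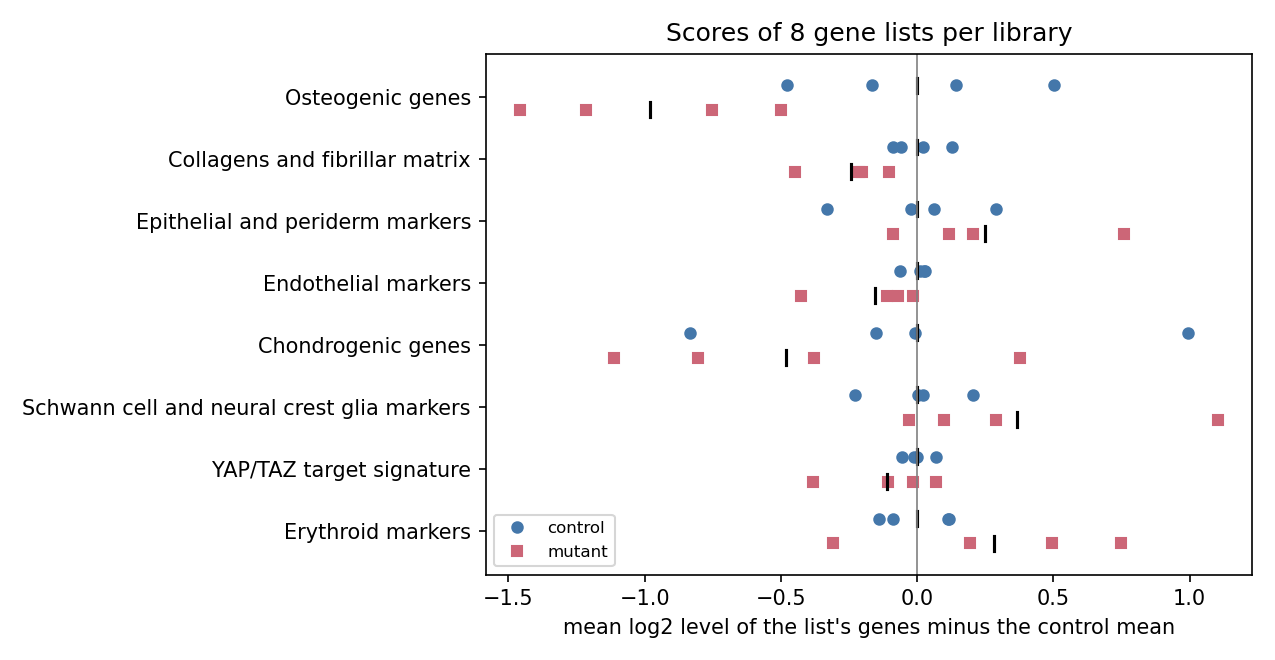
Mean log2 level of the tested genes of 8 lists (x axis, minus the mean of the control libraries) in the 4 control libraries (circles) and 4 mutant libraries (squares), with a black bar at each group mean. The osteogenic list has the widest gap between the group means, a difference of -0.98.

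The remaining cell type lists did not pass camera. Their adjusted p was 0.239 for macrophages (C1qa, a complement subunit, log2 difference 0.35), 0.839 for skeletal muscle (Ttn, titin, -0.44, and Myog, myogenin, 0.25), 0.839 for pericytes (Cspg4, -0.33), 0.839 for osteoclasts (Acp5, 0.86), 0.894 for neurons (Map2, 0.27, and Gap43, -0.19) and 0.901 for dental epithelium (Sp6, 0.41, and Msx2, -0.61). The melanocyte list had 4 tested members, under the minimum of 5, with log2 differences from 0.04 for Kit to 1.45 for Dct. Single libraries carried several of these values. Without mutant replicate 2 Msx2 was at -0.14, Map2 at 0.077 and Sp6 at 0.27. Ttn was at -0.029 without mutant replicate 4 and -0.72 without mutant replicate 3, Gap43 at -0.094 without control replicate 2, and Acp5 at 0.37 and Dct at 0.67 without control replicate 1. The skeletal muscle list spread widely among the mutant libraries, with a mean log2 level relative to controls from -1.03 in mutant replicate 4 to 0.84 in mutant replicate 3.

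None of the 5 signalling and patterning lists passed camera or held a gene that passed over all genes. In the WNT list (camera adjusted p = 0.894) the secreted inhibitor genes Wif1 and Dkk1 fell and the ligand Wnt6 rose when adjusted over the list alone. Wif1 had 766 ± 108 normalised counts in controls and 529 ± 54.0 in mutants, Dkk1 240 ± 99.1 and 81.6 ± 53.4, and Wnt6 552 ± 91.1 and 903 ± 260. The Hedgehog list (camera adjusted p = 0.781) included Shh, the secreted ligand of the pathway, at a log2 difference of 0.36 (SE 0.176, and 0.23 without mutant replicate 2). The TGF-beta and BMP list had 20 of 31 members lower (camera adjusted p = 0.0992), with Smad9 at -0.67 (SE 0.251) and Bmp2 at -0.38 (SE 0.144), which without mutant replicate 2 were at -0.35 and -0.23. The FGF list (camera adjusted p = 0.839) included Fgf18 at -0.24 (SE 0.0915). Palatal mesenchyme patterning genes divided into 15 higher and 17 lower (camera adjusted p = 0.846), with the T-box genes Tbx2 and Tbx22 at log2 differences of 0.28 (SE 0.0781) and 0.30 (SE 0.136) and Fgf7 at -0.43 (SE 0.192). Tbx22 was at 0.20 without control replicate 3 or without mutant replicate 4.

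Lists for the cell's mechanics, growth and stress did not pass either. Cald1, caldesmon, an actin-binding regulator of contraction, was the 1 actomyosin gene that fell when adjusted over the list alone, from 19844 ± 650 to 16545 ± 714 (camera adjusted p = 0.159 for the list), and the non-muscle myosin gene Myh10 had a log2 difference of -0.22 (SE 0.0773), and -0.14 without control replicate 3. Camera adjusted p was 0.839 for integrins and focal adhesion (Itga10, log2 difference -1.07), for basement membrane (Col18a1, 0.23, and Lama5, 0.42) and for hyaluronan and its proteoglycans (Cemip, -0.67), and without mutant replicate 2 Lama5 was at 0.26 and Cemip at -0.36. Cell cycle genes divided into 20 higher and 15 lower (camera adjusted p = 0.401), with Cdc20 at 0.16 (SE 0.0633), Ccnd1 at -0.19 (SE 0.0740) and Mybl2 at 0.17 (SE 0.0726). Camera adjusted p was 0.0763 for both the interferon response (Rsad2, log2 difference 2.33, with a mean of 10.9 in controls) and p53 targets (Btg2, 0.43), 0.369 for hypoxia and glycolysis (Gapdh, -0.19) and 0.501 for immediate early genes (Ier2, 0.28). The median, mean and camera direction of a list differed in sign for the WNT, FGF, hyaluronan, basement membrane, pericyte, osteoclast and neuronal lists, none of which passed.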

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

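All of these values were found by a search run after the data were seen. In 226 groups of 4 libraries, 1 library lay far from the other 3 in 11 groups, and chance alone gives about 1 in 20 groups. No explanation was tested for these values.

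Among control libraries, P4ha1 was at 5767.3 normalised counts in replicate 2 (others 4811 to 4945) and Cldn7 at 212.8 in the same library (others 440.8 to 476.3). Cdh5 was at 5744.7 in control replicate 1 (others 6396 to 6520). Control replicate 3 had Hba-a2 at 1685.6 (others 945 to 1058) and Hmgb1 at 341.6 (others 1375 to 1403), and the mean log2 level of the integrin and focal adhesion list there was 0.0467 (others -0.02 to -0.01). Msx2 was at 725.7 in control replicate 4 (others 1342 to 1468).

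Among mutant libraries, Erbb3 was at 2050.2 in replicate 4 (others 3134 to 3160) and Foxd3 at 292.7 in replicate 1 (others 153 to 177). Mutant replicate 2 had Smad9 at 289.6 (others 684 to 722) and Cemip at 109.8 (others 252 to 275).

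Xist, which no comparison used, was at 840.4 normalised counts in mutant replicate 2 and at 0 to 17.4 in the other 7 libraries. The Y-linked gene Ddx3y was at 2228 to 2920 normalised counts in all 8 libraries, mutant replicate 2 included. Whether that library held tissue of both sexes was not tested. It is also the library without which the epithelial list lost its call (camera adjusted p = 0.0881), the erythroid list lost its call (0.150) and the endothelial list kept it narrowly (0.0472).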

How the results depend on the processing

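The alternatives with the stabilised values, exact permutation of list means and list members with a mean of at least 50 were chosen after seeing the data; the others were planned. Yap1 and Wwtr1 kept their direction and stayed short of the threshold under all 22 alternatives run for them, with log2 differences from -0.22 to -0.15 and -0.37 to -0.22. Against 4 genes called, robust variances gave 0, with 0 changed 2-fold and 1061 at an unadjusted p below 0.05. DESeq2 gave 31 genes, 15 of them 2-fold. The stabilised values gave 3 genes and 0 changed 2-fold, on a scale that compresses differences by construction. Leaving out 1 library gave 0 to 11 genes and 0 to 11 changed 2-fold: 0 without control replicate 2, control replicate 4 or mutant replicate 3, 11 without control replicate 3, 8 without mutant replicate 4 (1 higher, 7 lower), and 2 changed 2-fold without control replicate 1. Apart from the stabilised scale, the cause was not tested. Quantile normalisation gave Gm42418 a difference of 0, since it gives the top gene of each library the same value.

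The first number of the titles as a block gave 6 genes, 2 of them among the 4 called, and 4 changed 2-fold. With the 6 libraries whose number occurs in both groups, the block gave 10 genes, 7 of them 2-fold, all 4 called genes included. Both blocks called 10 lists and lost the Schwann cell list (camera adjusted p = 0.171 and 0.168). Deviations of libraries that share a number across the groups were correlated over genes, which are not independent replicates. The values were -0.01 and 0.03 for one number and 0.00 and 0.10 for the other. The 0.10, of control replicate 3 with mutant replicate 3, was the highest of any pair across the groups. So few small values do not decide whether the numbers paired the samples.

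Against 8 lists called, camera with an estimated correlation gave 0, fry 0 and exact permutation of the list means 0, and leaving out 1 library gave 6 to 10. Leaving out 1 library moved the log2 difference by over 1.5 times in 28 of 84 named genes, in 17 of them without mutant replicate 2. Of the named genes run under these alternatives, Myog and Kit turned. Kit went from 0.04 to -0.0084 with library weights and ran from -0.089 without mutant replicate 4 to 0.19 when 1 library was left out. Myog went from 0.25 to a log2 difference of -0.068 without mutant replicate 3, the highest such value being 0.52 without mutant replicate 4, and neither gene passed the threshold under any alternative. Sex as a covariate was not run, since all 8 libraries held Y-linked reads, though the Xist reads of mutant replicate 2 leave the make-up of that library unsettled. Scaling moved the median of all genes by less than 0.01 on the log2 scale. Depth limits genes with few reads, of which Rsad2 had a mean of 10.9 in controls.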

Other observations

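Of the 31 genes that DESeq2 called on the recovered reads, the following 7, which limma did not call with all libraries and no block, were chosen after the values were seen. Phex is a member of the osteogenic list, and the other 6 belong to no list fixed in advance. Slit3 and Plxna4, which act in guidance of axons and vessels, had 2573 ± 209 and 1009 ± 153 normalised counts (SD, n = 4) in controls and 1908 ± 273 and 644 ± 112 in mutants. Phospho1, a phosphatase of matrix mineralisation, had 169 ± 54.3 and 53.9 ± 19.7, and Prelp, a leucine-rich repeat matrix protein gene, had 490 ± 118 and 240 ± 87.5. Thbd, thrombomodulin, had 812 ± 71.2 and 577 ± 71.0. Slit3, Plxna4, Phospho1, Prelp and Thbd were each lower in every mutant library than in every control library. A lack of overlap in either direction was seen in 3.77% of all genes tested, against 2.86% by chance. Their limma adjusted p ran from 0.576 for Phospho1 to 0.751 for Prelp among these 5 of the 7 genes.

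Limma called Plxna4 with the title number as a block, and Hmgb1 and Phex without control replicate 3. Control replicate 3 has the same first title number, 3602, as mutant replicates 2 and 3. It stood with the mutant libraries for Hmgb1 and Phex, as it did for Cgref1 and Loxl4. It also lay inside the mutant range for Dkk1 (101.6 normalised counts), Col11a2 (612.5) and Itga10 (97.5). For Ibsp it lay above every mutant library, at 6533.3 against 5680.4 in the highest. Hmgb1 was at 341.6 normalised counts in control replicate 3, at 1375 to 1403 in the other 3 controls and at 310 to 363 in mutants. Phex, a regulator of phosphate and bone mineral, was at 59.5 there, at 267 to 330 in the other 3 controls and at 57.7 to 68.1 in mutants. Mutant replicate 4 shares its first title number, 2057, with control replicates 2 and 4. It was at 343.9 for Hmgb1, against 1397.9 and 1374.9 in those controls, and at 57.7 for Phex, against 266.5 and 330. Neither gene therefore followed the title number alone.

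The tests on histone genes, late osteoblast genes, the title number, neuronal markers with Lsamp and the osteogenic level with Lsamp were chosen only after the result was seen. The margins by which values had to pass their bounds, and the term fitted for neuronal markers, were also set after the first values were seen, and the margins left the comparison of the osteogenic level with Gm42418 undecided. Correlations were taken over the 8 libraries with each group's mean removed, 8 in all, with exact permutation within groups. How the libraries were prepared, and whether the groups were prepared together, is not given in the sources used here. No library carried the Cre without the floxed alleles, so an effect of the Cre transgene itself stays open for all 3 patterns, as does the genotype.

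The ribosomal RNA locus and the 7SK RNA gene Rn7sk were lower in every mutant library. Control libraries may have kept more RNA without a poly(A) tail: histone genes, whose messages lack one, had a median log2 difference of -0.80 (40 of 45 lower, exact permutation p = 0.0286 for their mean), while the cell cycle list had a mean of 0.02. Within groups Gm42418 went with Rn7sk, r = 0.83 (permutation p = 0.0104, Benjamini-Hochberg 0.0833; Spearman rho = 0.71, permutation p = 0.0747; r = 0.38 without the 2 libraries farthest from the median), and with CT010467.1, r = 0.82 (permutation p = 0.0347, Benjamini-Hochberg 0.139; Spearman rho = 0.71, permutation p = 0.113; r = 0.30 without those 2), but neither passed after adjustment and both rested in part on those 2 libraries. The histone mean was not shown to follow Gm42418, which leaves a shared cause per library undecided, with r = 0.60 (permutation p = 0.215, Benjamini-Hochberg 0.306; Spearman rho = 0.36, permutation p = 0.458) and r = -0.66 without the 2 libraries farthest from the median. Whether 1 ribosomal RNA signal was counted at several loci, with CT010467.1, Gm23935 and Lars2 set against Gm42418, stayed undecided. The smallest correlation with Gm42418 was that of Gm23935, r = 0.59 (permutation p = 0.229, Benjamini-Hochberg 0.306; Spearman rho = 0.57, permutation p = 0.201), and r = -0.11 without the 2 libraries farthest from the median. Lars2 had r = 0.60 (permutation p = 0.148, Benjamini-Hochberg 0.295; Spearman rho = 0.55, permutation p = 0.227), and r = 0.48 without the 2 farthest.

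The osteogenic list was lower in every mutant library, and without mutant replicate 2, which had the lowest level, the difference went from -0.98 to -0.82. The title number as a term left a difference of -0.67 (SE 0.175), with -0.49 and -0.86 within the 2 numbers found in both groups, which argues against that number as the whole cause. A smaller share of osteoblast-lineage tissue could lower all its genes alike, but late osteoblast genes relative to Sp7 differed by -0.58 (10 genes, SE 0.296, exact permutation p = 0.114), which does not decide it, and 4 of the 23 tested list members stand in another list too. Markers of other tissues moved both ways beside it, with mean differences of 0.25 for epithelium and -0.16 for endothelium, and no test tied the osteogenic difference to them. The osteogenic level did not follow Gm42418 clearly, with r = -0.12 (permutation p = 0.816, Benjamini-Hochberg 0.816; Spearman rho = -0.05, permutation p = 0.941) and r = 0.04 without the 2 farthest libraries, and a fit with Gm42418 as a term left -1.28 (SE 1.12), too wide to tell these apart.

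Lsamp was lower in every mutant library. The 21 other tested genes within 2 Mb of Lsamp had a median log2 difference of -0.061 (SD 0.298, lowest -0.27), which argues against an effect on the whole neighbourhood but not against one inside the gene, such as a transgene inserted there. Less nervous tissue would lower neuronal markers with Lsamp. With the neuronal level as a term the Lsamp difference was -1.62 (SE 0.153). That level hardly differed between the groups, by -0.02, so the term could hardly move the difference and the fit decides nothing. The -0.02 itself decided nothing either, since it was -0.44 without control replicate 3, -0.31 without mutant replicate 2 and 0.19 without control replicate 4. Within groups Lsamp went against the neuronal level, r = -0.77 (permutation p = 0.0538, Benjamini-Hochberg 0.144; Spearman rho = -0.79, permutation p = 0.0573; r = -0.83 without the 2 farthest libraries). This did not pass after adjustment, so whether less nervous tissue lowered Lsamp stayed undecided. With the osteogenic level as a term the Lsamp difference was -1.47 (SE 0.386). Within groups Lsamp did not clearly follow that level, r = 0.21 (permutation p = 0.665, Benjamini-Hochberg 0.760; Spearman rho = -0.02, permutation p = 0.979). Without the 2 farthest libraries r was -0.46. With so uncertain a relation the fit does not decide whether less osteoblast-lineage tissue lowered Lsamp. A lower level of Lsamp that follows from loss of Yap1 and Taz stays a hypothesis, found on these data, beside an effect of the transgene. No test here tells them apart.

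Of the 35 ways to divide the 8 libraries into 4 and 4, 2 gave as many as the 4 genes called, the real one included, so chance cannot be excluded for that count. The highest of the others was 4, for control replicates 1, 2 and 4 with mutant replicate 1 against the rest, which keeps the 3 libraries with one title number together, and the blocked counts were 6 and 10. For genes changed 2-fold, 1 of 35 gave the real 4 and the highest of the others was 1. That is the smallest share that 35 divisions can give, and it was not adjusted over the counts tried. Whether the non-coding genes among the 4 carried 1 shared signal stayed undecided. The 2-fold count also went to 0 with robust variances and without control replicate 2, control replicate 4 or mutant replicate 3. The share met the bound written before this result was seen, but given these limits chance was not taken as excluded for this count either. For gene lists chance cannot be excluded, since 12 of 35 gave as many as the real 8 and the highest of the others was 11.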
